A study of Mus musculus with 24 samples.

How the data were processed

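Small intestinal crypts and villi of mice of a mixed C57BL/6 and FVB background were profiled on 24 Affymetrix mouse arrays, 3 for each of 8 groups. The groups were WT, Rb, TKO (E2f1, E2f2 and E2f3 lost) and QKO (those and Rb lost), each as crypts and as villi, assigned from the labels. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 3 ug of it. The deposited values are log2 expression per probe set. How the authors summarised and normalized them is not given in the sources used here. They range from 2.29 to 14.9, and the array medians lie between 4.97 and 5.08 except for QKO crypts 2 (5.17) and QKO villi 3 (5.26). The number of arrays limits the precision, and the labels do not say whether arrays of a group came from separate animals. The TKO arrays of each compartment and the Rb villus arrays included both sexes, so each of these groups held more than 1 animal, and the QKO numbers paired crypts with villi by the values. In WT and in Rb crypts this stays open. The mean of 6 MHC class II genes read 11.23, 7.91 and 7.32 on the WT crypt arrays, 10.39, 8.50 and 9.40 on the WT villus arrays and 8.57, 9.46 and 7.35 on the Rb crypt arrays. This argues against repeats of 1 RNA, but not against several preparations of 1 animal. The p-values there may thus not measure the spread between animals.

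Of 45101 probe sets, 34945 had 1 gene in the platform annotation, 932 had several, 9160 were named by no gene here and 64 were controls. Symbols of 34741 probe sets were updated through their Entrez identifier and 204 kept the file's symbol. The 18193 genes were each represented by the probe set with the highest mean over all arrays. Other probe sets of a gene can disagree with it, as the targeted genes show. All value columns were used. The values were already on a log2 scale and were not normalized again, no dim gene was removed, and no offset was added.

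Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 24 arrays, moderated variances with an intensity trend (residual df 16, prior df 4.86), 2-sided tests and Benjamini-Hochberg adjustment within each of 15 comparisons. A gene was called at an adjusted p under 0.05. Differences between compartments or genotypes of a difference were tested as contrasts of the same fit. On simulated data for TKO minus WT in villi, with 18193 genes, 37.3% of genes changed by 0.5 were called, 82.1% of those changed by 1, 100% of those changed by 2 and 0.0111% of unchanged genes. For the TKO difference in villi minus crypts the shares were 4.48%, 67.2%, 95.5% and 0.0445%. The simulated values were normal and independent between genes and arrays, with the same SD for a gene on all arrays. Only 67, 67 and 66 genes were changed by 0.5, 1 and 2. Correlated genes, unequal spread between arrays and paired TKO arrays were left out, so these shares need not hold for the real data.

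Gene lists of pathways and cell types were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. Of 435 gene list tests over 29 lists with at least 5 measured members, 162 were called, and 26 with an estimated correlation. The lists, the comparisons, the tests, the alternatives and the rule for named genes were chosen before the data were examined, except where a setting is said to have been chosen later. The rule named, for 6 main comparisons, the 5 called genes with the largest rise and the 5 with the largest fall. These had no overlap between the arrays of the groups compared and a higher group mean above 6.39, the median of all values. It added the 3 members with the smallest p from up to 6 called lists with the smallest p. For other comparisons it named 3 rises and 3 falls, and always Rb1 and E2f1 to E2f8. Predicted genes and Riken clones were left out of the largest changes. Not every gene the rule named is described.

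Replicates were compared before averaging: correlations within groups lay between 0.979 and 0.994, and 0 pairs held identical values. Replicate numbers were checked by correlating deviations from the group means between crypts and villi. Arrays with the same number correlated at 0.61, 0.55 and 0.64 in TKO and at 0.55, 0.25 and 0.37 in QKO, and each correlated best with its own number, so the numbers pair crypts with villi in these genotypes. The pairing comes from the values and not from the labels. In WT the correlations were 0.01, 0.13 and 0, and in Rb 0.06, -0.01 and -0.24, so the numbers do not pair there. Figures were drawn with matplotlib 3.10.9.

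Alternatives were quantile normalization, centring on array medians, no intensity trend, removal of dim genes (10072 left), the mean of a gene's probe sets, every probe set tested, only the groups compared, array weights, replicate blocks and leaving out each array. A further 4 were chosen after seeing the data: leaving out WT crypts 3 and Rb crypts 2, leaving out QKO villi 3 and QKO crypts 2, sex as a covariate, and the replicate number as a random block within TKO and QKO. The annotation table of genes was used only for names and for which genes neighbour each other.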

Results

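RNA of small intestinal crypts and villi from mice of 4 genotypes was measured on 24 Affymetrix arrays, which read each transcript through sets of short DNA probes. Crypts are the pits that hold stem cells and dividing cells, and villi are the folds covered by cells that have left the cell cycle. The genotypes were wild type (WT), loss of Rb (Rb), loss of E2f1, E2f2 and E2f3 (TKO), and loss of all 4 genes (QKO). Each genotype was profiled in both compartments with 3 arrays per group. The mice were 2 months old, and tissue was taken 7 days after an intraperitoneal dose of beta-naphthoflavone, a ligand of the aryl hydrocarbon receptor. Rb binds E2f transcription factors, which control genes of DNA replication and division. The comparisons ask what E2f1 to E2f3 do in dividing and in differentiated cells, and how the loss of Rb alters this. Fold changes are given as log2 differences ± SE, with adjusted p from limma. The SE comes from the fit over all 24 arrays, so it pools the spread of all groups and not only of those compared.

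The Rb1 probe set with the stronger signal checked the Rb labels. In villi it read 10.70, 10.93 and 10.74 on the WT arrays and 8.84, 9.36 and 9.19 on the Rb arrays. In QKO it read 8.13 to 8.23 in crypts and 8.28 to 8.77 in villi, below all TKO arrays. In crypts 1 array of each group went against its label: the array labelled WT crypts 3 read 8.46, beside 10.31 and 10.59, and the array labelled Rb crypts 2 read 10.25, beside 8.23 and 8.87. Every statement on WT or Rb crypts therefore refers to the arrays so labelled. The second Rb1 probe set was near the bottom of the scale and differed by 0.45 ± 0.12 in Rb minus WT villi (adjusted p = 0.016), against the direction of the first. E2f2, by its brighter probe set, was lower in TKO than in WT crypts (-1.01 ± 0.19, adjusted p = 0.0018), and its villus difference of 0.36 ± 0.19 was not called (adjusted p = 0.32). The 3 probe sets of E2f1 disagreed: 1 was lower in TKO crypts (-0.71 ± 0.17, adjusted p = 0.011) and higher in TKO villi (0.94 ± 0.17, adjusted p = 0.0011), whereas the differences of the other two were not called in either. Neither E2f3 probe set differed by the test. A probe set outside the deleted part of a gene checks nothing, and the deleted parts are not given in the sources used here.

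**Figure D1:**
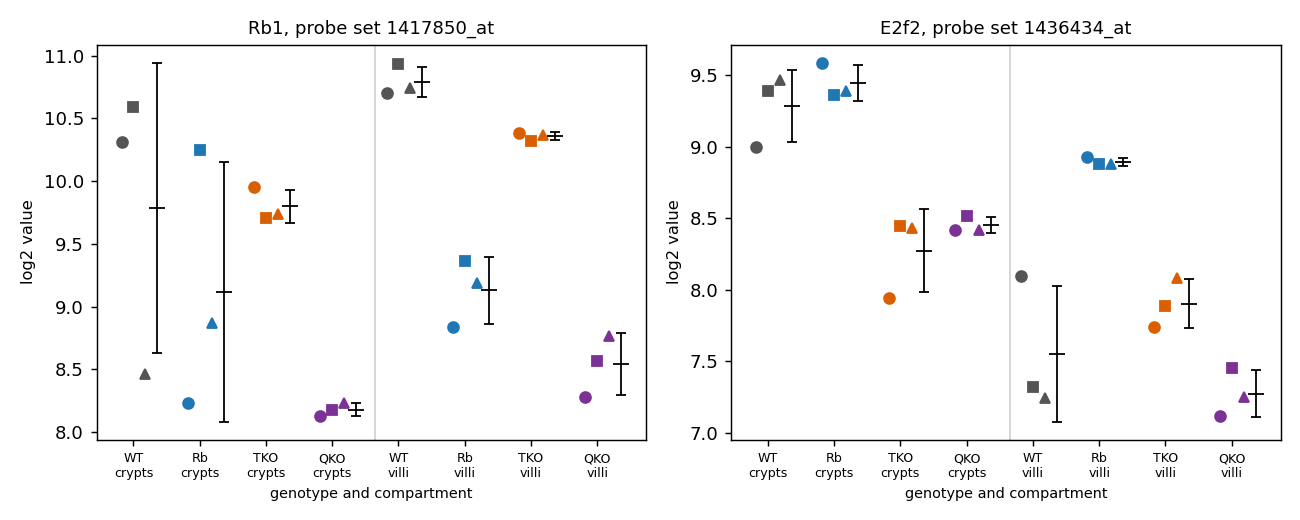
Log2 level of Rb1 and E2f2, each by its brighter probe set, on each array, by group, with the mean ± SD of 3 arrays and the replicate number as marker shape. The array labelled WT crypts 3 sits at 8.46 and the array labelled Rb crypts 2 at 10.25 for Rb1, each among the values of the other label.

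Bacterial poly-A controls, which are added to RNA before labelling, split the arrays by E2f status. Their mean was 5.79 ± 0.45 (SD, n = 12 arrays) over WT and Rb and 9.90 ± 0.66 (SD, n = 12) over TKO and QKO, and the ranges of 5.18 to 6.67 and 8.97 to 10.91 did not overlap. Each comparison of TKO or QKO with WT or Rb lies across this split. No batch holds both sides of such a comparison, so batch and E2f status cannot be told apart there. Rb minus WT and QKO minus TKO lie within it, but the QKO villus arrays (10.41 to 10.91) also read above the TKO villus arrays (9.70 to 9.92). The hybridization controls had means of 10.84 in WT crypts and 10.19 in WT villi, and of 10.82 and 10.13 in Rb. Villi minus crypts therefore also lies across a technical difference in these genotypes. The Y-linked gene Eif2s3y showed that all WT arrays and all Rb crypt arrays came from females, and that all QKO arrays came from males. Males also gave 2 of 3 Rb villus arrays and 2 of 3 TKO arrays of each compartment. Sex and genotype therefore cannot be told apart in QKO minus WT or in QKO minus Rb crypts.

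**Figure D2:**
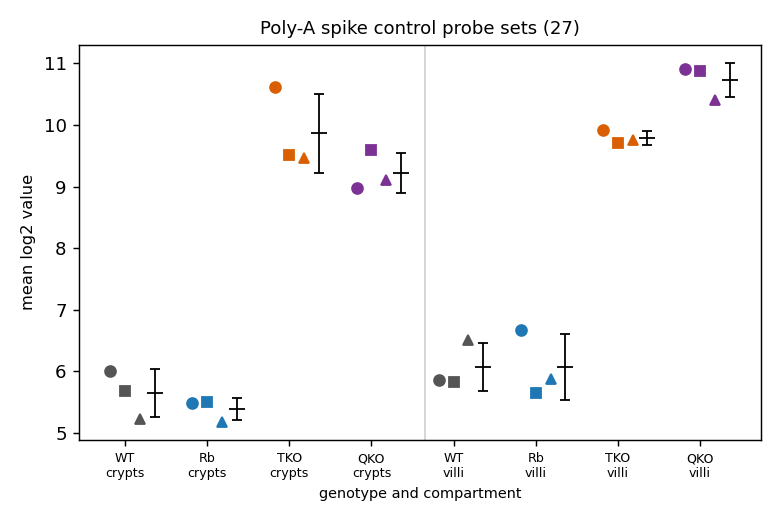
Mean log2 level of the poly-A spike controls on each array, by group, with the mean ± SD of 3 arrays and the replicate number as marker shape. The WT and Rb arrays lie between 5.18 and 6.67 and the TKO and QKO arrays between 8.97 and 10.91.

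Genes of division and ribosome production were lower in WT villi than in WT crypts, and genes of nutrient absorption were higher. Of 56 measured genes of the G1/S transition and DNA replication, most of them textbook E2f targets, 52 were lower and 0 higher (53 and 0 adjusted over the list alone), with a median of -1.97 (list adjusted p = 1.1e-39, and adjusted p = 0.048 with an estimated correlation). The helicase genes Mcm7 and Mcm5 fell by 2.59 ± 0.14 and 2.86 ± 0.17. Of 57 G2/M and mitosis genes 54 were lower and 1 higher, also adjusted over the list alone, with a median of -2.40 (adjusted p = 1.3e-38, and adjusted p = 0.11 with an estimated correlation); the mitotic kinesin Kif20b differed by -3.10 ± 0.19. Of 30 ribosome biogenesis genes 29 were lower, also over the list alone (median -1.84, adjusted p = 2.4e-22, and adjusted p = 0.13 with an estimated correlation), among them the nucleolin gene Ncl (-2.47 ± 0.23). Of 22 stem cell markers 19 were lower, as over the list alone, where 1 was also higher (median -1.43, adjusted p = 4.6e-09, and adjusted p = 0.25 with an estimated correlation), such as Smoc2 (-2.62 ± 0.33) and Sox9 (-2.14 ± 0.31). Of 43 enterocyte genes 36 were higher and 0 lower (40 and 0 adjusted over the list alone), with a median of 0.97 (adjusted p = 5.8e-11, and adjusted p = 0.25 with an estimated correlation), including the glucose transporter gene Slc2a2 (2.12 ± 0.35). The largest rises were in Pdk4, a kinase of pyruvate dehydrogenase (19.5-fold), and Cyp1a1, an aryl hydrocarbon receptor target (17.0-fold). In all 6803 of 18193 genes were called, 3417 higher and 3386 lower, which is 50.2% higher. With arrays centred on their medians 70.0% were higher, and the median of all genes moved by 0.15.

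Cell cycle genes were higher in Rb than in WT villi. All but 2 of the 56 G1/S genes were higher, 54 against 0 lower (55 and 0 adjusted over the list alone), with a median of 2.03 (adjusted p = 6.5e-79, and adjusted p = 0.0042 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 3.82 ± 0.28 (14.1-fold) and the primase gene Prim1 by 3.32 ± 0.23. Of 57 G2/M genes 54 were higher and 1 lower, also over the list alone (median 1.80, adjusted p = 1.5e-57, and adjusted p = 0.032 with an estimated correlation), with Cdk1 at 2.41 ± 0.20. Of 26 DNA damage checkpoint and repair genes 20 were higher (25 adjusted over the list alone; median 1.0, adjusted p = 4.9e-27, and adjusted p = 0.0056 with an estimated correlation), with Brca1 at 3.06 ± 0.25. Of 30 ribosome biogenesis genes 12 were higher and 1 lower (19 and 1 adjusted over the list alone; median 0.61, adjusted p = 1.3e-08, and adjusted p = 0.52 with an estimated correlation). Of 13 E2f and pocket protein genes 9 were higher and 1 lower, as over the list alone (median 0.78, adjusted p = 3.2e-08, and adjusted p = 0.0044 with an estimated correlation); the atypical E2f genes E2f7 and E2f8 rose by 3.11 ± 0.30 and 3.10 ± 0.30, and E2f2 by 1.35 ± 0.19. Of 13 genes of D cyclins, G1 kinases and their inhibitors 7 were higher (10 over the list alone; median 0.79, adjusted p = 1.8e-07, and adjusted p = 0.0014 with an estimated correlation), among them Cdk2 (1.98 ± 0.19) and the kinase inhibitor gene Cdkn2c (2.67 ± 0.27). Of 26 enteroendocrine markers 9 were lower and 0 higher (13 and 0 adjusted over the list alone; median -0.75, adjusted p = 4.1e-06, and adjusted p = 0.5 with an estimated correlation). The water channel gene Aqp8 (-2.33 ± 0.59) and Serpina1c (-2.35 ± 0.47) were among the largest falls. In all 2690 genes were called, 1563 higher and 1127 lower. The share higher was 58.1%, against 48.6% with arrays centred on their medians and 47.3% with array weights. Without WT villi 3 or Rb villi 3 the count was 1751 or 1745, and with sex as a covariate, chosen after seeing the data, 1704.

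In crypts no gene was called between the arrays labelled Rb and WT by limma. An unadjusted p under 0.05 was found for 709 of 18193 genes, where 910 are expected with no change. The G1/S list was called higher with a median of 0.12 and 0 members called, also over the list alone (adjusted p = 0.0012, and adjusted p = 0.93 with an estimated correlation). Its call was lost without WT crypts 1 (median 0.035, adjusted p = 0.19), WT crypts 2 (0.047, adjusted p = 0.26) or Rb crypts 1 (0.016, adjusted p = 0.68). The ribosome biogenesis list was called lower (median -0.20, adjusted p = 1.5e-05, and adjusted p = 0.92 with an estimated correlation), as was the stem cell list (median -0.28, adjusted p = 0.00014, and adjusted p = 0.92 with an estimated correlation). T cell markers were called lower (median -0.36, adjusted p = 0.0017, and adjusted p = 0.92 with an estimated correlation). Endothelial markers were called higher (median 0.15, adjusted p = 0.0039, and adjusted p = 0.58 with an estimated correlation). Without the arrays labelled WT crypts 3 and Rb crypts 2, a setting chosen after seeing the data, 18 genes were called. The G1/S median was then 0.32 with 5 members higher and 0 lower (adjusted p = 7.6e-16). The ribosome biogenesis median was -0.55 (adjusted p = 6.6e-17) and the stem cell median -0.77 (adjusted p = 2.1e-11). The T cell and endothelial calls were lost (medians -0.24 and 0.12, adjusted p = 0.15 each). The Rb difference itself differed between compartments: 950 genes were called for Rb minus WT in villi minus that in crypts, 749 higher and 201 lower. The G1/S list had 48 members higher and 0 lower (55 and 0 adjusted over the list alone), with a median of 1.84 (adjusted p = 7.7e-76, and adjusted p = 0.0051 with an estimated correlation), led by Zfp367 (3.61 ± 0.52) and Rrm2 (3.43 ± 0.40). Of these 950 genes 78.8% were higher, against 58.4% with arrays centred on their medians and 69.0% after quantile normalization. Without WT villi 3 or Rb villi 3, 629 or 601 were called, and with sex as a covariate 592. Without the arrays labelled WT crypts 3 and Rb crypts 2, the G1/S median of this difference between compartments was 1.56. There 42 members were higher and 0 lower (list adjusted p = 1e-61 with camera).

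**Figure D3:**
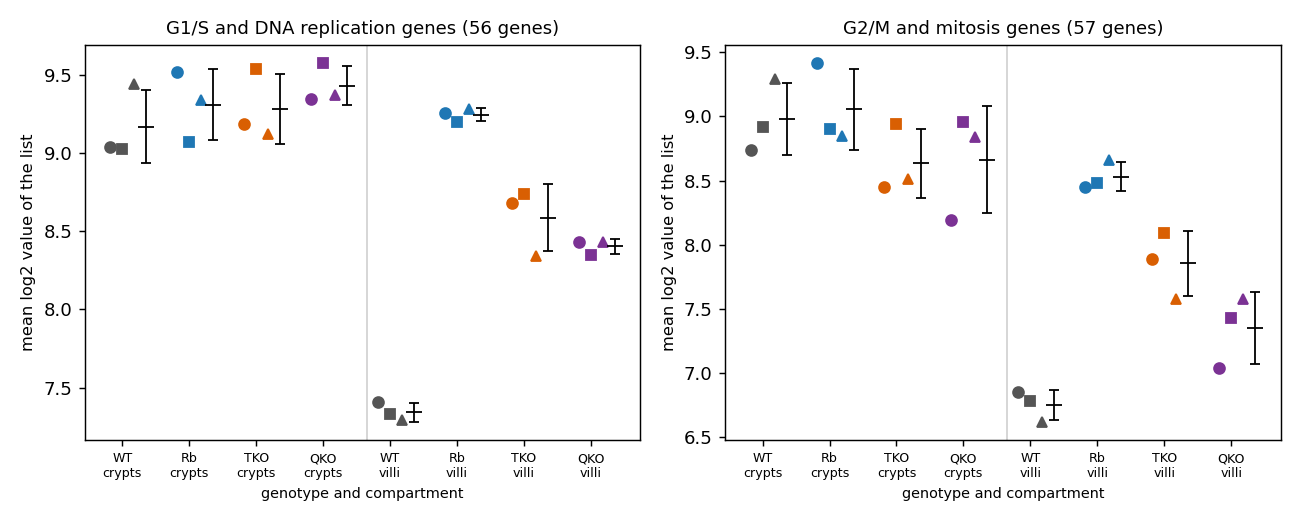
Mean log2 level of the G1/S genes and of the G2/M genes on each array, by group, with the mean ± SD of 3 arrays and the replicate number as marker shape. The G1/S mean was 7.34 ± 0.06 in WT villi, 9.25 ± 0.04 in Rb villi, 8.59 ± 0.22 in TKO villi and 8.40 ± 0.05 in QKO villi.

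Goblet cell markers were lower in TKO than in WT crypts. Of 20 markers 11 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.79 (adjusted p = 3.8e-12, and adjusted p = 0.11 with an estimated correlation). The mucin gene Muc2 fell by 1.12 ± 0.19, Tff3 by 1.02 ± 0.15 and Atoh1, a transcription factor of secretory cells, by 1.14 ± 0.17. Of the G2/M genes 7 were lower and 1 higher (10 and 2 adjusted over the list alone; median -0.34, adjusted p = 3.5e-06, and adjusted p = 0.79 with an estimated correlation), with Mki67 at -1.48 ± 0.29. The G1/S list was called higher with 7 members higher and 2 lower (10 and 3 adjusted over the list alone), at a median of 0.14 (adjusted p = 0.027, and adjusted p = 0.79 with an estimated correlation). That call was lost without WT crypts 1 (median 0.085, adjusted p = 0.22), WT crypts 2 (0.13, adjusted p = 0.29) or TKO crypts 2 (0.035, adjusted p = 0.7). Without the arrays labelled WT crypts 3 and Rb crypts 2, the G1/S median was 0.23 with 7 higher and 0 lower (adjusted p = 1.3e-05). The G2/M median was then -0.15 with 1 higher and 2 lower (adjusted p = 0.016), and 7 goblet markers were lower and 0 higher (median -0.84, adjusted p = 3.1e-10). T cell markers had a median of -0.87, with 2 of 19 lower (6 over the list alone; adjusted p = 2.2e-05, and adjusted p = 0.79 with an estimated correlation), and 4 lower at a median of -1.12 without those arrays. E2f7 was lower (-2.07 ± 0.30, adjusted p = 0.0006). The phospholipase gene Pla2g2a (-5.51 ± 0.44), the eosinophil ribonuclease gene Ear3 (-6.41 ± 0.29) and Cdkn2c (-3.53 ± 0.27) were among the largest falls, and Rbp7 (4.26 ± 0.31), Mbl2 (4.20 ± 0.49) and Rnase1 (3.75 ± 0.27) rose. In all 861 genes were called, 351 higher and 510 lower. Without WT crypts 2, WT crypts 3, TKO crypts 1 or TKO crypts 3 the count was 346, 426, 370 or 401.

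In villi the same genotype had higher cell cycle genes. Of the 56 G1/S genes 49 were higher and 0 lower, also over the list alone, with a median of 1.35 (adjusted p = 2.6e-60, and adjusted p = 0.014 with an estimated correlation); Mcm5 rose by 2.34 ± 0.17 and Mcm7 by 1.92 ± 0.14. Of the G2/M genes 44 were higher and 0 lower (50 and 0 adjusted over the list alone; median 1.16, adjusted p = 5.3e-38, and adjusted p = 0.097 with an estimated correlation), with Mad2l1, a gene of the spindle checkpoint, at 1.77 ± 0.17. The DNA damage list had 21 of 26 members higher (24 over the list alone; median 1.06, adjusted p = 3.9e-27, and adjusted p = 0.014 with an estimated correlation), and the ribosome biogenesis list 25 of 30 (29 over the list alone; median 1.01, adjusted p = 4e-25, and adjusted p = 0.097 with an estimated correlation). Of 22 stem cell markers 6 were higher and 0 lower (8 and 0 over the list alone; median 0.47, adjusted p = 0.00096, and adjusted p = 0.66 with an estimated correlation). Goblet markers were lower here too, 9 of 20 and 0 higher (9 and 1 over the list alone), with a median of -0.46 (adjusted p = 1.1e-06, and adjusted p = 0.13 with an estimated correlation); Fcgbp differed by -1.49 ± 0.22 and Muc2 by -1.29 ± 0.19. E2f8 rose by 1.75 ± 0.30, and Cyp2c55 (-3.54 ± 0.37), Ear3 (-5.57 ± 0.29) and Pla2g2a (-4.84 ± 0.44) fell. In all 1778 genes were called, 1129 higher and 649 lower, or 63.5% higher against 38.0% with arrays centred on their medians. Without WT villi 3 or TKO villi 2 the count was 1110 or 1024, and with sex as a covariate 1167.

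The TKO difference in villi exceeded that in crypts for the cell cycle lists. For TKO minus WT in villi minus that in crypts, 38 G1/S genes were higher and 0 lower (48 and 0 adjusted over the list alone), with a median of 1.16 (adjusted p = 3.9e-47, and adjusted p = 0.027 with an estimated correlation). The G2/M list had 42 higher and 0 lower (53 and 1 adjusted over the list alone; median 1.53, adjusted p = 3.4e-48, and adjusted p = 0.056 with an estimated correlation). Without the arrays labelled WT crypts 3 and Rb crypts 2, the G1/S median was 1.08 with 35 higher and 0 lower. The G2/M median was then 1.36 with 32 higher and 0 lower. Over all arrays E2f2 differed by 1.37 ± 0.26, E2f7 by 1.93 ± 0.42 and E2f8 by 1.96 ± 0.42. Here 624 genes were called, 490 higher and 134 lower, or 78.5% higher against 47.0% with arrays centred on their medians, which moved the median of all genes by -0.12. Without WT crypts 2, WT villi 3, TKO villi 1, TKO villi 2, TKO crypts 1 or TKO crypts 3 the count was 385, 288, 414, 280, 268 or 351. Over genes the TKO differences in crypts and villi correlated with r = 0.39 and rho = 0.23, where genes are not independent replicates and TKO arrays with the same number correlated between compartments. Of 238 genes called in both, 121 were higher in both and 97 lower in both, where independent lists would give 21.8 and 18.2, and 20 went opposite ways.

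Cell cycle genes were lower in QKO than in Rb villi. There 48 G2/M genes were lower and 0 higher (51 and 0 adjusted over the list alone), with a median of -1.18 (adjusted p = 2.5e-33, and adjusted p = 0.13 with an estimated correlation); Mki67 fell by 3.08 ± 0.29 and Top2a by 2.31 ± 0.27. Of the G1/S genes 39 were lower and 1 higher (44 and 1 adjusted over the list alone), with a median of -0.76 (adjusted p = 2.7e-26, and adjusted p = 0.13 with an estimated correlation), among them the replication clamp gene Pcna (-1.74 ± 0.17). The E2f and pocket protein list had 7 of 13 lower, also over the list alone (median -0.73, adjusted p = 5.9e-08, and adjusted p = 0.015 with an estimated correlation), with E2f7 at -3.64 ± 0.30. Enteroendocrine markers rose: 20 of 26 were higher and 0 lower, also over the list alone, with a median of 2.3 (adjusted p = 4.7e-17, and adjusted p = 0.099 with an estimated correlation). Tph1, which makes serotonin, rose by 3.98 ± 0.31, Scg2 by 3.26 ± 0.26 and the secretin gene Sct by 2.40 ± 0.21. The part of the intestine sampled is not given, and whether it bears on this rise was not tested. Goblet markers were lower, 12 of 20 and 0 higher (14 and 1 over the list alone; median -0.59, adjusted p = 4.7e-07, and adjusted p = 0.13 with an estimated correlation). On the same arrays T cell markers were higher (11 of 19, 15 over the list alone; median 1.35, adjusted p = 1.5e-05, and adjusted p = 0.5 with an estimated correlation), as were fibroblast and muscle markers (8 of 24, 10 over the list alone; median 0.68, adjusted p = 0.0044, and adjusted p = 0.61 with an estimated correlation). Without QKO villi 3 and QKO crypts 2, chosen after seeing the data, 6 T cell markers were higher with a median of 1.15 (adjusted p = 0.00013). Of the fibroblast and muscle markers 4 were then higher, with a median of 0.30 (adjusted p = 0.026). The largest changes included Anxa10 (4.90 ± 0.31), the calcium channel gene Trpv6 (4.20 ± 0.40), Cdkn2c (-4.45 ± 0.27) and Pla2g2a (-6.62 ± 0.44). In all 4043 genes were called, 2584 higher and 1459 lower. The share higher was 63.9%, against 34.5% with arrays centred on their medians and 47.0% after quantile normalization. Centring moved the median of all genes by -0.17.

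**Figure D4:**
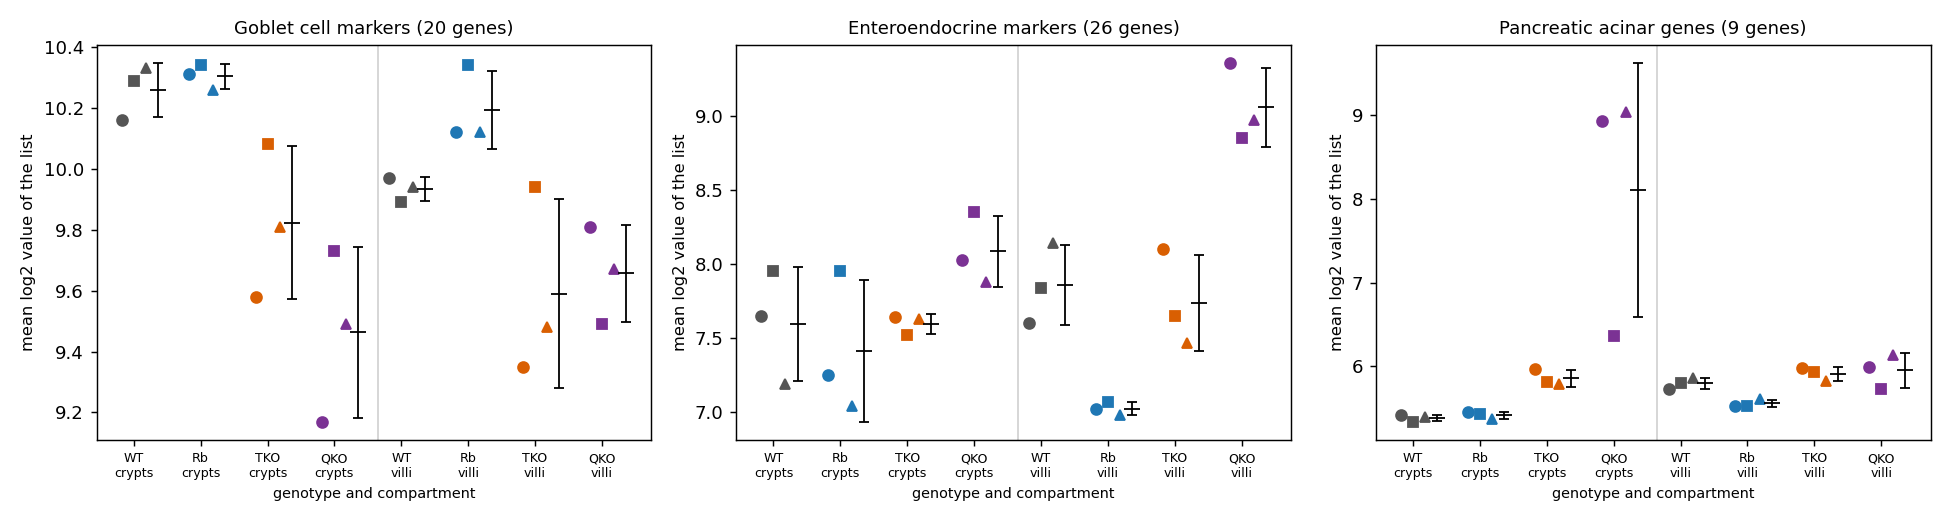
Mean log2 level of goblet cell, enteroendocrine cell and pancreatic acinar markers on each array, by group, with the mean ± SD of 3 arrays and the replicate number as marker shape. Enteroendocrine markers were at 9.06 ± 0.27 in QKO villi and 7.02 ± 0.05 in Rb villi, and acinar markers spread from 6.36 to 9.04 over the QKO crypt arrays.

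In QKO minus Rb crypts, 13 goblet markers were lower and 0 higher (14 and 0 adjusted over the list alone), with a median of -0.96 (adjusted p = 3.8e-14, and adjusted p = 0.065 with an estimated correlation). All 9 measured pancreatic acinar genes were higher, also over the list alone, with a median of 2.51 (adjusted p = 1.9e-09, and adjusted p = 0.19 with an estimated correlation). Their mean was 8.11 ± 1.52 (SD, n = 3) in QKO crypts and 5.42 ± 0.04 (SD, n = 3) in Rb crypts. It read 8.93, 6.36 and 9.04 on QKO crypts 1, 2 and 3. The acinar list stands for a cell type that a preparation could hold, and carry-over of pancreas was not tested. The same QKO arrays enter QKO minus TKO and QKO minus WT in crypts, so this limit and its share in the called genes hold there too. Enteroendocrine markers had 11 higher and 1 lower (13 and 1 over the list alone; median 0.78, adjusted p = 0.0036, and adjusted p = 0.65 with an estimated correlation). T cell markers had 5 of 19 lower, also over the list alone (median -0.80, adjusted p = 3.4e-05, and adjusted p = 0.58 with an estimated correlation). Paneth cell markers had 1 of 11 lower (2 over the list alone; median -0.82, adjusted p = 0.0026, and adjusted p = 0.58 with an estimated correlation). Without WT crypts 3 and Rb crypts 2 the Paneth median was -0.33 (adjusted p = 0.026), and 9 T cell markers were lower. Without QKO villi 3 and QKO crypts 2, 4 enteroendocrine markers were higher and 1 T cell marker was lower. G2/M genes had 11 lower and 1 higher (17 and 2 over the list alone; median -0.41, adjusted p = 3.2e-08, and adjusted p = 0.63 with an estimated correlation). E2f2 (-0.99 ± 0.19) and E2f7 (-2.19 ± 0.30) were lower. The Y-linked genes Eif2s3y (6.63 ± 1.53) and Uty (4.68 ± 1.10) were among the largest rises, beside Rbp7 (5.15 ± 0.31), and Clca4a (-6.05 ± 0.49) was among the largest falls. In all 3128 genes were called, 2441 higher and 687 lower, or 78.0% higher against 50.8% after quantile normalization and 41.2% with arrays centred on their medians, which moved the median of all genes by -0.16. Without QKO crypts 2 the count was 1964, and with sex as a covariate 1605. That covariate rests on the TKO and Rb villus arrays, the groups with both sexes. It does not separate sex from genotype in this comparison, where all QKO arrays were male and all Rb arrays female. Across genes the difference correlated with TKO minus WT in crypts at r = 0.59, and 93.7% of the genes called there had the same sign, while in villi r was 0.02 and the share 51.5%.

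QKO and TKO arrays lie on 1 side of the poly-A split, but in villi their control levels did not overlap. The hybridization controls there read 11.17 ± 0.11 in QKO and 10.63 ± 0.11 in TKO (SD, n = 3 each), so a technical difference between these groups was not excluded. In villi 18 enteroendocrine markers were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 1.60 (adjusted p = 1.1e-15, and adjusted p = 0.37 with an estimated correlation). G2/M genes had 7 lower and 0 higher (9 and 0 over the list alone; median -0.55, adjusted p = 4.3e-17, and adjusted p = 0.52 with an estimated correlation), and G1/S genes 3 and 0, also over the list alone (median -0.21, adjusted p = 9e-06, and adjusted p = 0.54 with an estimated correlation). T cell markers had 7 higher (12 over the list alone; median 1.15, adjusted p = 4.4e-08, and adjusted p = 0.52 with an estimated correlation). Without QKO villi 3 and QKO crypts 2, 2 G2/M genes and 1 G1/S gene were lower (medians -0.66 and -0.22). There 1 T cell marker was higher (median 0.98), as were 2 of 24 fibroblast and muscle markers (median 0.41, list adjusted p = 0.011 with camera). Over all arrays the mean of the fibroblast and muscle markers was 6.13 ± 0.62 in QKO villi and 5.21 ± 0.07 in TKO villi (SD, n = 3 each). Rb1 differed by -1.82 ± 0.41 (adjusted p = 0.01), Anxa10 by 5.21 ± 0.31 and the calcium-binding protein gene S100g by 4.39 ± 0.55. Here 1215 genes were called, 1003 higher and 212 lower, or 82.6% higher against 58.1% after quantile normalization and 52.1% with arrays centred on their medians, which moved the median of all genes by -0.12. Without TKO villi 1, TKO villi 2 or QKO villi 3 the count was 794, 531 or 586. With only the groups compared fitted it was 145. In crypts 292 genes were called, 259 higher and 33 lower, or 88.7% higher against 58.5% after quantile normalization and 37.5% with arrays centred on their medians, which moved the median of all genes by -0.15. Of these Ear3 differed by 5.68 ± 0.29, Ccnb1ip1 by 4.45 ± 0.33 and Pmp22 by -3.61 ± 0.65, and 8 acinar genes were higher, also over the list alone (median 2.19, adjusted p = 2.8e-11, and adjusted p = 0.32 with an estimated correlation). Without TKO crypts 1, TKO crypts 3, QKO crypts 1 or QKO crypts 2 the crypt count was 100, 108, 125 or 93. With only the groups compared fitted it was 63.

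The Rb difference in villi was not the same with and without E2f1 to E2f3. For QKO minus TKO minus the Rb minus WT difference, 51 G1/S genes were lower and 0 higher (55 and 0 adjusted over the list alone), with a median of -2.22 (adjusted p = 1.2e-69, and adjusted p = 0.0051 with an estimated correlation); Rrm2 differed by -4.29 ± 0.40. G2/M genes had 53 lower, also over the list alone (median -2.41, adjusted p = 8e-60, and adjusted p = 0.028 with an estimated correlation). E2f7 and E2f8 differed by -3.49 ± 0.42 and -3.62 ± 0.42, and Tph1 by 4.65 ± 0.44 within an enteroendocrine list of 18 higher and 0 lower (20 and 0 over the list alone; median 2.42, adjusted p = 4.4e-14, and adjusted p = 0.09 with an estimated correlation). T cell markers had 6 higher (10 over the list alone; median 1.37, adjusted p = 6.3e-05, and adjusted p = 0.6 with an estimated correlation). Fibroblast and muscle markers had 5 higher (6 over the list alone; median 0.78, adjusted p = 0.0086, and adjusted p = 0.6 with an estimated correlation). Without QKO villi 3 and QKO crypts 2, each had 3 higher, with medians of 1.15 (adjusted p = 0.00023) and 0.45 (adjusted p = 0.031). In all 2808 genes were called, 1621 higher and 1187 lower, or 57.7% higher against 47.1% with arrays centred on their medians and 47.7% after quantile normalization, which moved the median of all genes by -0.11. In crypts 5 genes were called, 4 higher and 1 lower, or 80% higher against 50% after quantile normalization and 18.2% with arrays centred on their medians, which moved the median of all genes by -0.18. Ear3 (5.75 ± 0.41), Ccnb1ip1 (4.52 ± 0.46) and Anxa10 (2.70 ± 0.44, chosen after its values were seen) were higher. Without Rb crypts 1 or TKO crypts 2 only 2 genes were called, so at least 1 of these also lost its call. Tbcel (1.02 ± 0.16) was called with adjusted p = 0.014, which became 0.076 without Rb crypts 1 and 0.052 without TKO crypts 2. St3gal4 (-12.06 ± 2.03) was called with adjusted p = 0.025, which lay between 0.05 and 0.1 without any of WT crypts 2, WT crypts 3, Rb crypts 1, Rb crypts 3, TKO crypts 1, TKO crypts 2 or QKO crypts 1. The crypt count was 3 without WT crypts 2 or QKO crypts 1, 2 without Rb crypts 1 or TKO crypts 2, 10 without Rb crypts 2 or TKO crypts 3, 21 without QKO crypts 2 and 20 without QKO crypts 3. With the replicate number as a block it was 14.

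Against WT, QKO villi had higher G1/S genes, 42 and 0 lower (46 and 0 adjusted over the list alone), with a median of 1.14 (adjusted p = 6.3e-33, and adjusted p = 0.17 with an estimated correlation). Enteroendocrine markers had 18 higher and 1 lower, as over the list alone (median 1.36, adjusted p = 3.6e-10, and adjusted p = 0.4 with an estimated correlation), and T cell markers 8 higher (9 over the list alone; median 1.07, adjusted p = 0.00021, and adjusted p = 0.71 with an estimated correlation). Without QKO villi 3 and QKO crypts 2, 3 T cell markers were higher (median 0.82, adjusted p = 0.0048). Anxa10 rose by 5.96 ± 0.31. Of 3052 genes called 2104 were higher and 948 lower, or 68.9% higher against 46.5% after quantile normalization and 23.5% with arrays centred on their medians, which moved the median of all genes by -0.21. In crypts 15 goblet markers were lower and 1 higher (16 and 1 over the list alone), with a median of -0.96 (adjusted p = 4.2e-16, and adjusted p = 0.039 with an estimated correlation). Paneth cell markers had 4 of 11 lower (7 over the list alone; median -1.30, adjusted p = 1.4e-05, and adjusted p = 0.3 with an estimated correlation), or 2 lower without QKO villi 3 and QKO crypts 2. T cell markers had 9 lower (12 and 1 higher over the list alone; median -1.16, adjusted p = 3.9e-10, and adjusted p = 0.3 with an estimated correlation), and all 9 acinar genes were higher (median 2.81, adjusted p = 1.2e-10, and adjusted p = 0.21 with an estimated correlation). Of 2428 genes called in crypts 1872 were higher and 556 lower, or 77.1% higher against 51.1% after quantile normalization and 49.4% with arrays centred on their medians, which moved the median of all genes by -0.12. Without WT villi 3 the villus count was 1956, and without WT crypts 3 or QKO crypts 2 the crypt count was 1583 or 1430. With sex as a covariate the villus and crypt counts were 1242 and 1171. All WT arrays were female and all QKO arrays male, so these counts do not separate sex from genotype.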

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

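The batch tests, both for the G1/S list and for the genes called alike in TKO, the sex test, the splits that keep TKO pairs together and the settings that leave out doubted arrays were chosen only after the results were seen. Groups of 3 arrays were not tested for outliers.

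The TKO difference was not the same in villi and crypts by a test of that difference, which called 624 genes and gave the G1/S list a median of 1.16. Of 100 splits drawn, 3 called as many genes, the real one included. The highest other split called 723 and exchanged WT crypts 3 with TKO crypts 2. Both others as large kept the villus arrays as labelled. TKO numbers pair crypts with villi, and of the 28 splits that keep these pairs together 1 called as many, with 0 as the highest other. Exchanged labels put the real genotype differences into the spread, which lowers the counts. Neither set of splits can therefore exclude chance. The Rb difference also differed between compartments. Its test called 950 genes, with a G1/S median of 1.84 (1.56 without the arrays labelled WT crypts 3 and Rb crypts 2). Of 100 splits, 10 called as many and the highest other called 1470, so by that share chance cannot be excluded for the count. All 9 others kept the villus arrays as labelled, and where neither compartment was as labelled the highest count was 2, so they vary the crypt arrays and not the villus difference. The highest split exchanged the arrays labelled WT crypts 3 and Rb crypts 2, which points to a structure of these samples. The Rb difference depended on E2f status in villi, with 2808 genes and a G1/S median of -2.22. Of 100 splits 1 called as many and the highest other called 1645. These splits also put the real genotype differences into the spread, so they cannot exclude chance. In crypts the same test called 5 genes. Of 100 splits 15 called as many and the highest other called 258, so chance cannot be excluded. That split held the same exchange, but it also gave all TKO crypt arrays the QKO label and the reverse. It therefore added the Rb difference with E2f1 to E2f3 to that without them, and did not contrast them.

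The poly-A controls, which no comparison uses, had a mean of 9.90 over the TKO and QKO arrays and 5.79 over the WT and Rb arrays.

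G1/S genes were higher in Rb, TKO and QKO villi than in WT villi. Whole crypts carried over into villus preparations would bring Paneth and stem cell transcripts in the same share. Taking WT crypts as the source, the median share of those markers was 5.30% (95% bootstrap interval over genes -0.376 to 13.5) in Rb, 8.56% (-0.809 to 28.5) in TKO and -0.331% (-8.21 to 11.4) in QKO. For the G1/S genes it was 97.5%, 51.5% and 42.7%, which argues against carry-over of whole crypts as the whole cause. The intervals resample genes and not arrays, so they leave out the spread between arrays. Carry-over of dividing crypt cells without Paneth and stem cells was not tested. With each genotype's own crypts as the source the marker and G1/S shares were 28.1% (21.0 to 30.1) and 44.7% (43.6 to 46.8) in TKO. In QKO they were 10.7% (1.65 to 19) and 29.8% (26.1 to 33.3). In Rb they were 14% (-0.71 to 17.3) and 88.5% (78.2 to 105). Of 22 stem cell markers 6 were higher in TKO villi (median 0.47), against 0 of 11 Paneth markers. A partial share may therefore remain, in QKO as well as in TKO. A batch shift shared by both compartments would cancel in villi minus crypts, where the TKO median was 1.16 (0.97 to 1.35 over genes). A batch shift confined to villi stays open, as does an effect of genotype. The hybridization controls read 10.84 in WT crypts and 10.19 in WT villi, against 10.44 in TKO crypts and 10.63 in TKO villi. A technical difference therefore need not cancel.

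Rb1 went against the label on 1 WT and 1 Rb crypt array. If these labels had been exchanged, 868 other genes called between Rb and WT villi, and little different between WT crypts and villi, would place them on the wrong side as well. The score of the array labelled WT crypts 3 was 0.041 and that of the array labelled Rb crypts 2 was -0.062, a difference of 0.103, while the other WT crypt arrays scored -0.107 and -0.088 and the other Rb crypt arrays 0.054 and 0.163. This is consistent with an exchange of these labels. The split of the 6 arrays that exchanges them called 103 genes, and the split as labelled 0. Incomplete deletion of Rb1 in single animals was not tested.

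In TKO, 218 genes were called in the same direction in crypts and villi. A strain haplotype carried along with the knockout alleles would place them near the targeted genes: 17 of 599 neighbours of E2f1, E2f2 and E2f3 were among them against 199 of 17542 genes elsewhere (odds ratio 2.55, interval 1.44 to 4.22, Fisher's exact test, one-sided p = 0.00086). Of these, 11 lay among 199 neighbours of E2f2. Pla2g2a, which also lies near E2f2, and the targeted genes were left out of the test. A haplotype may account for some of the 17, and the test does not limit it to them. Genes elsewhere were not tested for a haplotype. Among them was Ear3, which was lower in TKO than in WT crypts but higher in QKO than in TKO crypts. For sex, the genes were called again without TKO 1 and 1 WT number in turn (64, 33 and 42 genes), and TKO 1 minus that WT number, both from females, went in the called direction in both compartments in at least 89.1% of them, which argues against sex as the cause for most of these. Batch and genotype cannot be told apart, because each batch holds 1 side of the comparison; 95% of the genes had the same sign in QKO minus Rb in crypts and 82.6% in villi, which lie across the same batches.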

How the results depend on the processing

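Of the main counts and list medians, 302 values over all settings stayed on their side of the threshold or within 1.5 times, 74 counts moved by more and 9 list calls were lost. The main numbers follow the settings, and the cause was not tested unless named. Signal near the bottom of the scale limits genes with few transcripts. The offset on the log scale listed beforehand was not run, since the values were already log2. Settings that leave out 2 arrays, sex as a covariate and the block within TKO and QKO were chosen after seeing the data.

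Quantile normalization gave 159 genes for QKO minus TKO, crypts and 8 for Rb by E2f interaction, crypts (main 292 and 5). Centring gave 33 for Rb by E2f interaction, crypts and 5360 for QKO minus WT, villi. With the mean of probe sets, Rb by E2f interaction, crypts had 2 genes and the G1S list median log2 fold change, TKO minus WT, crypts was 0.12 (adjusted p = 0.082). Testing every probe set, which tests more features, gave 2381 for TKO minus WT, crypts, 1429 for TKO effect, villi minus crypts, 4717 for QKO minus Rb, crypts, 12 for Rb by E2f interaction, crypts and 3835 for QKO minus WT, crypts. Fitting only the groups compared, with fewer arrays to estimate the spread, gave 483 for TKO minus WT, crypts, 4265 for Rb minus WT, villi, 1212 for QKO minus Rb, crypts, 2622 for QKO minus Rb, villi, 63 for QKO minus TKO, crypts, 145 for QKO minus TKO, villi, 3 for Rb by E2f interaction, crypts and 1673 for QKO minus WT, villi; the G1S list median log2 fold change, TKO minus WT, crypts was 0.14 (adjusted p = 0.056). Array weights gave 1802 for TKO minus WT, crypts, 3280 for TKO minus WT, villi, 1611 for TKO effect, villi minus crypts, 5109 for Rb minus WT, villi, 1896 for Rb effect, villi minus crypts and 57 for Rb by E2f interaction, crypts.

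With the replicate number as a block, Rb by E2f interaction, crypts had 14 genes, and no other count moved by over 1.5 times; as a random block within TKO and QKO it had 8. Where numbers do not pair the arrays, in WT and Rb, 1 of 3 WT arrays and 1 of 3 Rb arrays correlated best with their own number. Without WT crypts 3 and Rb crypts 2, TKO minus WT, crypts had 489, Rb minus WT, crypts 18 and Rb by E2f interaction, crypts 25. Without QKO villi 3 and QKO crypts 2, QKO minus TKO, crypts had 106, QKO minus TKO, villi 653 and Rb by E2f interaction, crypts 25. With sex as a covariate, TKO minus WT, villi had 1167, Rb minus WT, villi 1704, Rb effect, villi minus crypts 592, QKO minus Rb, crypts 1605, QKO minus WT, crypts 1171 and QKO minus WT, villi 1242, and the G1S list median log2 fold change, TKO minus WT, crypts was 0.14 (adjusted p = 0.13). In QKO minus Rb, crypts and QKO minus WT, each sex holds 1 side, so the covariate does not separate sex from genotype there. The gene list tests went from 162 calls to 26 with an estimated correlation: the G1/S, DNA damage, and cyclin and kinase lists in WT villi minus WT crypts; these, the E2f list and the G2/M list in Rb minus WT, villi, Rb effect, villi minus crypts and Rb by E2f interaction, villi; these without G2/M in TKO effect, villi minus crypts; G1/S and DNA damage in TKO minus WT, villi; the E2f list in QKO minus Rb, villi; and goblet markers in QKO minus WT, crypts.

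Leaving out each array in turn gave 5478 to 6229 genes for WT villi minus WT crypts, 346 to 832 for TKO minus WT, crypts, 1024 to 1712 for TKO minus WT, villi, 268 to 821 for TKO effect, villi minus crypts, 0 for Rb minus WT, crypts, 1745 to 2163 for Rb minus WT, villi, 601 to 896 for Rb effect, villi minus crypts, 1964 to 2885 for QKO minus Rb, crypts, 2868 to 4069 for QKO minus Rb, villi, 93 to 417 for QKO minus TKO, crypts, 531 to 1607 for QKO minus TKO, villi, 2 to 21 for Rb by E2f interaction, crypts, 2041 to 3410 for Rb by E2f interaction, villi, 1430 to 2240 for QKO minus WT, crypts and 1956 to 2809 for QKO minus WT, villi. The G1/S median ranged from 0.035 to 0.24 in TKO minus WT, crypts, 1.25 to 1.48 in TKO minus WT, villi, 0.016 to 0.23 in Rb minus WT, crypts, 2.00 to 2.07 in Rb minus WT, villi and -0.80 to -0.72 in QKO minus Rb, villi.

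Of named genes, 197 values lost their call, 90 of them outside the settings that leave out 1 array, 43 gained one and 2 changed sign: with the mean of probe sets, E2f6 log2 fold change, QKO minus Rb, crypts was -0.11 and E2f6 log2 fold change, QKO minus WT, crypts was -0.12, where that gene's probe sets disagree.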

Other observations

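The region markers were chosen after the named genes were seen.

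The calcium channel gene Trpv6 (4.20 ± 0.40), the calcium-binding protein gene S100g (3.02 ± 0.55), the iron reductase gene Cybrd1 (3.33 ± 0.23) and the iron exporter gene Slc40a1 (3.21 ± 0.40) were higher in QKO than in Rb villi. The other 4 of 8 markers of the proximal intestine, Gata4 (0.21 ± 0.17), Onecut2 (0.32 ± 0.29), Fabp1 (-0.16 ± 0.15) and Lct (-0.07 ± 0.19), were not called. Of 7 distal markers 4 were lower: Plb1 (-4.08 ± 0.81), Osr2 (-1.10 ± 0.32), Fabp6 (-2.46 ± 0.84) and Slc10a2 (-0.74 ± 0.22). The last pair was not called against WT villi (adjusted p = 0.17 and 0.71), and Slc10a2 was higher in Rb than in WT villi (0.89 ± 0.22). The bile acid carrier genes Slc51a (-0.05 ± 0.21) and Slc51b (-0.30 ± 0.38) were not called, nor was Cubn (0 ± 1.05). These markers were picked with some of their values known, so they do not test a shift along the intestine. Which part of it was sampled is not given in the sources used here. The enteroendocrine differences of QKO villi from Rb, TKO and WT villi come from the same QKO arrays. Whether the part sampled bears on them was not tested.

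Tuft cell markers were lower in TKO than in WT villi, 4 of 15 and 0 higher (9 and 0 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.00016, and adjusted p = 0.26 with an estimated correlation). In QKO minus TKO villi 7 were higher (8 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.00023, and adjusted p = 0.52 with an estimated correlation). Genes of lipid absorption were higher in WT villi than in WT crypts, 18 of 24 and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.80 (adjusted p = 3.4e-06, and adjusted p = 0.25 with an estimated correlation).

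With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the real split is 1 of them. The real count and the highest count of another split were 6803 and 1 for WT villi minus crypts, 861 and 0 for TKO minus WT in crypts, 1778 and 0 for it in villi, and 2690 and 0 for Rb minus WT in villi. For QKO minus Rb they were 3128 and 0 in crypts and 4043 and 1 in villi, for QKO minus TKO 292 and 0 and 1215 and 63, and for QKO minus WT 2428 and 0 and 3052 and 1. For Rb minus WT in crypts the real count was 0, all 10 splits called as many, and the highest other called 103.

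Rb minus WT and QKO minus TKO in villi correlated across genes with r = -0.18, and 37.8% of the genes called in the first had the same sign in the second. Both lie within the poly-A split, though the QKO villus arrays read higher than the TKO villus arrays in these controls.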
